A study of Drosophila melanogaster with 4 samples.

How the data were processed

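Hairy ChIP DNA and input DNA from embryos labelled as 0 to 8 h old were sequenced in 2 libraries each, numbered 1 and 2 per the labels. Per the labels' protocols, embryos were fixed in 1.8% formaldehyde for 15 min. The stage label of 0 to 8 h and the collection protocol, which names a laying of 8 to 16 h, differ, so the age of the embryos is uncertain. One file was analysed, a peak list for the whole series. Per the file headers it uses FlyBase release 5 coordinates, and each of its lines names MACS as the source. Per the submitters' processing notes, CASAVA 1.7.0.2 and 1.7.0.3, BWA and MACS2 were used with the build BDGP5, and the role and order of these tools are not given in the sources used here. Whether peaks were called on pooled replicates, against which control, with which threshold and with which treatment of duplicate or multiply mapping reads is not given in the sources used here. These steps decide which peaks are listed and how peaks in repeated sequence score.

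The deposited score of each peak is used as the authors gave it. The list does not say whether it is a p-value, a q-value, a fold enrichment or another quantity, so scores were compared only within the list. Spearman correlations use their order alone, whereas differences of medians, means of block medians, the Pearson correlation and the mean of log2 scores use their size, and the autosomal scores multiplied by a factor in the closing tests of the X treat them as proportional to signal, which the list does not show. The start and end of each peak are other values the authors deposited, 1-based and inclusive. On the listed values, no peaks overlapped, the smallest gap between neighbours was 50 bp, and 205 peaks had the smallest width of 201 bp. The read depth of the libraries is unknown from this list, so no interval for a peak's own strength is given, and a region without a peak is one that did not pass the authors' threshold. The list gives no value per library, so no comparison between replicates, or between ChIP and input, was made here. Whether the 2 libraries of a group came from separate collections is not given either.

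Groups were taken from the sample titles. The tests, gene lists, named items and alternatives were fixed before the data were examined, except those said to be added. The annotation table at hand is for Release 6 of the genome. Coordinates were not converted between builds, so the planned analyses of transcription start sites, gene features, gene lists and sequence motifs were not run, and no peak was assigned to a gene. The rule for this case, also fixed beforehand, was to name the 20 peaks with the highest scores and the 5 densest 100 kb windows. The 3R window rich in strong peaks, the peaks of chromosome 4, the comparisons of other sequences with the large autosomal arms, the 1 kb distance, the X rates by score and the medians of width by score were added after the values were seen. Release 5 lengths of 2L, 2R, 3L, 3R, 4 and X were entered from general knowledge of that assembly. The end of the last peak on each arm was tried as the length instead.

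The number of peaks per arm was tested against arm length with exact binomial tests and Benjamini-Hochberg adjustment over the 6 arms. Clustering was measured as the share of peaks whose nearest neighbour lay within 10 kb between midpoints, against 1000 random placements of the same peak widths without overlap on the same arm. Peaks per window were counted by midpoint in adjacent 100 kb windows from base 1. The fullest random window was taken from 10 more sets of 1000 placements, added because it changed between sets. Median scores were compared with two-sided permutation tests of 100000 resamples, or 10000 for the 6 comparisons of other sequences with the large autosomal arms (2L, 2R, 3L and 3R). Because neighbouring peaks are not independent, 1 Mb blocks were added as a unit, using complete blocks only, with block labels permuted 100000 times. Intervals are 95% Clopper-Pearson intervals and cover counting error only. Rate ratios between the X and the large autosomal arms have exact intervals conditional on the total number of peaks.

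Alternatives were the 4479 peaks with the highest scores (13.18 and above), merging of touching peaks or of peaks within 500 bp, distances of 5 and 20 kb, 50 kb blocks, inclusion of all nuclear sequences, mean log2 score, and removal of the 1% widest peaks. Tests were run on simulated data first, with the 8099 peaks of the arms. Of 100 unclustered lists 4 were called clustered or dispersed, a number of lists set after a first, smaller set had given a higher share of calls, and 5 of 5 lists with added clusters were called clustered. An X simulated at a density of 0.8 was recovered at a mean of 0.798, and X scores multiplied by 0.9 were called lower in 10 of 10 runs. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.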

Results

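Chromatin bound by Hairy was profiled in Drosophila melanogaster embryos labelled as 0 to 8 h old by chromatin immunoprecipitation and sequencing (ChIP-seq). Hairy is a basic helix-loop-helix transcriptional repressor of the Hairy/Enhancer of split family and the product of a pair-rule segmentation gene. The embryos came from a strain marked with y, cn, bw and sp, and the antibody was a rabbit polyclonal serum raised against part of the Hairy protein. The series has 4 libraries, 2 of Hairy ChIP DNA and 2 of input DNA. The data analysed were a single list of 8958 Hairy peaks on Release 5 of the genome, with a start, an end and a score for each peak. The list carries no value per library, so the read depth is unknown and no value below has a replicate error. The score is the authors' own, its scale is not named in the list, and it is compared only within the list. The design asks where Hairy-bound chromatin lies in the embryo, at a stage labelled 0 to 8 h but described in the collection protocol as a laying of 8 to 16 h. Peaks are named by their coordinates because no gene annotation of Release 5 was used here.

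Most Hairy peaks lay on the assembled chromosome arms. Of the 8958 peaks, 8099 (90.4%) were on 2L, 2R, 3L, 3R, 4 and X, where they covered 3.35% of the sequence. A further 728 peaks were on Uextra, the collection of small unplaced scaffolds, 81 on the scaffolds of pericentric heterochromatin, 40 on U, the other unplaced sequence, and 10 on the mitochondrial genome. The list held no peak on a Y-chromosome sequence. The median peak was 378 bp wide, with quartiles of 268 and 571 bp and a range from 201 to 9316 bp. The median score was 13.2, the quartiles were 10.4 and 18.5, and the range ran from 5.93 to 676.3. Strong peaks were wider than weak ones. The 2265 peaks with scores at or above the upper quartile had a median width of 607 bp, against 264 bp for the 2241 peaks at or below the lower quartile. Across the 8958 peaks, score and width correlated with a Spearman rho of 0.60 and a Pearson r of 0.55 on log2 values (permutation p = 1e-05 for each, two-sided, the smallest that 100000 resamples can give). This correlation is across peaks, which are not independent replicates.

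The strongest Hairy peak of the list was on chromosome arm 2R at 17590146 to 17592468, with a score of 676.3 and a width of 2323 bp. On the same arm, a peak at 16771631 to 16772373 scored 439.46. On 3R the strongest peak, at 25541600 to 25544648, scored 430.92, and the next, at 12419740 to 12423264, scored 290.93. The strongest peak of the X, at 2553284 to 2555024, scored 288.75. A peak of 8320 bp on 2R at 9450462 to 9458781 scored 288.70, and its neighbour at 9447749 to 9449287 scored 145.65. The 20 highest-scoring peaks comprised 6 on 2R, 6 on 3R, 4 on the X, 1 on 2L, 2 on Uextra and 1 on U. Their scores ran from 145.65 to 676.3 and their median width was 1671 bp. Besides those above, the list of 20 held 3R 6490020 to 6491118 (score 246.80), X 13276988 to 13278930 (227.74), 2R 4814642 to 4816988 (179.88), X 16861378 to 16861967 (174.95), X 4400738 to 4401608 (172.46), 2R 15884532 to 15885831 (164.23) and 2L 18947194 to 18948017 (156.58). The unplaced peaks among the 20 lay at 28219758 to 28220379 (200.61) and 28549472 to 28549890 (150.94) on Uextra and at 5288464 to 5297779 (145.68) on U.

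The remaining 3 of the 20 strongest peaks lay together on 3R, at 21829652 to 21833293 (score 270.97), 21845747 to 21848416 (221.49) and 21824634 to 21826234 (162.10). The 100 kb window around them, from 21800001 to 21900000, held 23 peaks that covered 33.6% of it, the highest coverage of the 1208 windows on the arms. Of these 23 peaks, 10 were among the 90 peaks (1%) with the highest scores in the list, and no other 100 kb window on the arms held more than 2 of those 90. With windows shifted by 50 kb the group was divided, and the fullest window held 6. From the first to the last of the 10, over 42.0 kb between 21824634 and 21866624, peaks covered 65.2% of the sequence. The window with the next highest coverage was 9400001 to 9500000 on 2R, with 23 peaks covering 23.1%.

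**Figure D1:**
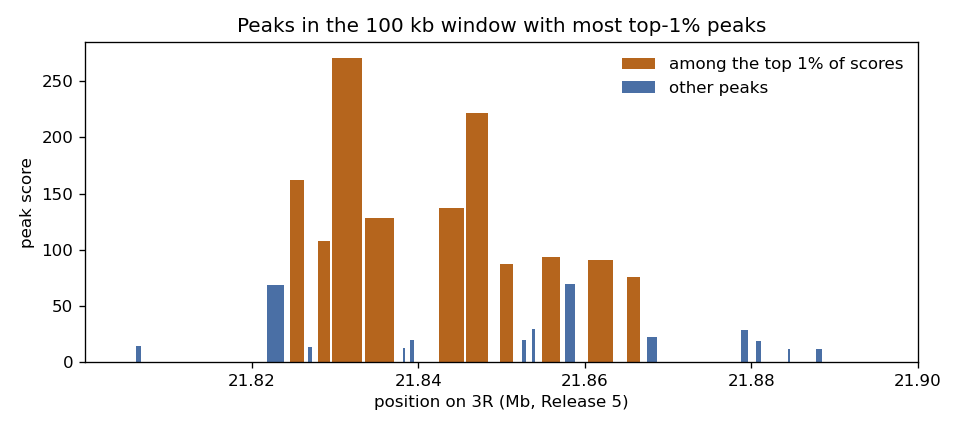
Score (vertical axis, the authors' unit) of each Hairy peak against its position on 3R in Mb (Release 5) in the window from 21800001 to 21900000. Each bar is 1 peak drawn to its width. The 10 orange bars are peaks among the 1% with the highest scores in the list, and the tallest reaches 270.97.

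The arms differed in their density of Hairy peaks. Arm 2R carried 82.8 peaks per Mb, 3R 70.6, 2L 63.0, 3L 61.9, the X 61.5 and the small, largely heterochromatic chromosome 4 carried 21.5. Against the share of arm length, 2R had 1.23 times the expected number of peaks (1751 observed, 95% Clopper-Pearson interval 1.18 to 1.28) and chromosome 4 had 0.32 times (29 observed, 0.21 to 0.46). The X had 0.91 times (1379 observed, 0.87 to 0.96), 3L 0.92 times, 2L 0.94 times and 3R 1.05 times. By exact binomial tests adjusted over the 6 arms, the departures gave adjusted p = 6.52e-20 for 2R, 1.76e-13 for chromosome 4, 0.000365 for the X, 0.000365 for 3L, 0.00645 for 2L and 0.0143 for 3R. These intervals and tests cover counting error only and treat neighbouring peaks as independent. The 6 ratios are also linked, because each expectation rests on the total over all arms. The surplus on 2R thus lowers the ratios of the other arms. The values below 1 on 2L, 3L and the X, which had like densities per Mb, may in part mirror it and are not separate depletions. When 1 Mb blocks were the unit, 2R still had more peaks than the other large autosomal arms (83.3 ± 28.6 per block, SD over 21 blocks, against 65.9 ± 23.7 over 74 blocks, permutation p = 0.00556). The X was then within the spread between blocks (62.6 ± 26.3 over 22 blocks against 69.8 ± 25.7 over 95, permutation p = 0.245), and chromosome 4 holds too few blocks for this test. Counts of 50 kb blocks with a peak gave 1.10 times for 2R (adjusted p = 0.114, exact binomial test) and 0.72 times for chromosome 4 (adjusted p = 0.451), so neither call held. Of the 2R blocks 85.1% had a peak, against a mean of 98.7% when the same peaks were placed at random, and the 2R ratio was above the random range of 1.00 to 1.04. With all nuclear sequences in the expectation, the directions of the X (1.15 times, adjusted p = 2.37e-08, exact binomial test), 3L (1.16 times) and 2L (1.18 times) were reversed.

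**Figure D2:**
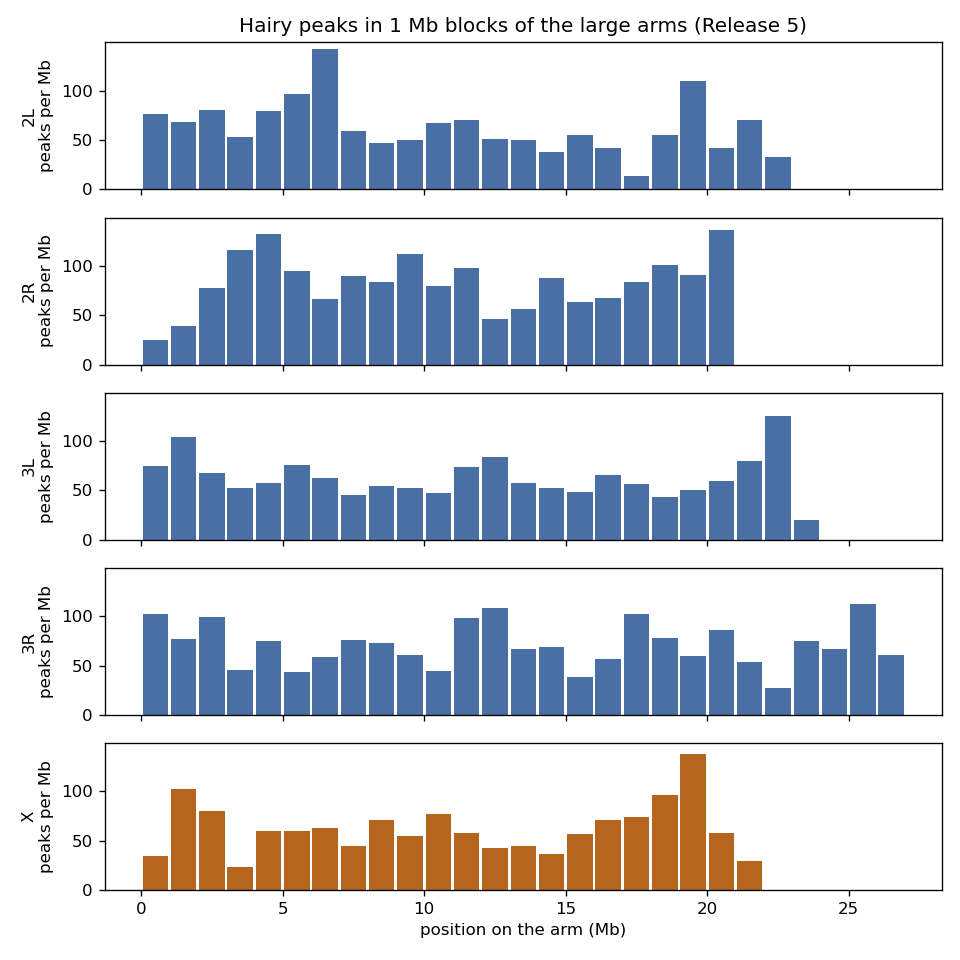
Number of Hairy peaks (vertical axis) in each complete 1 Mb block along 2L, 2R, 3L, 3R and X (horizontal axis, position in Mb, Release 5). Each bar is 1 of 117 blocks, and the counts run from 14 to 142.

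Peaks on the X scored lower than those on the autosomes. The median score was 12.0 for the 1379 X peaks and 12.9 for the 6720 peaks on 2L, 2R, 3L, 3R and 4, a difference of -0.93 (permutation test, two-sided, p = 1e-05, the smallest that 100000 resamples can give). Over 1 Mb blocks the median score was 12.1 ± 0.59 (SD, 22 blocks) on the X and 13.1 ± 0.99 (95 blocks) on the large autosomal arms, with a permutation p of 1e-05. By score, a comparison added after the values were seen, the X had fewer peaks per Mb at 15 or more and at 30 or more. Peaks that scored 15 or more numbered 17.6 per Mb on the X and 25.3 on the large autosomal arms, a rate ratio of 0.69 (exact 95% interval 0.62 to 0.77), and at 30 or more the ratio was 0.56 (0.40 to 0.76). At 50 or more it was 0.82 (16 X peaks, 0.45 to 1.41), an interval that includes equal rates and the ratios at 15 and 30. At 75 or more the X rate was the higher, with a ratio of 1.08 from 9 X peaks (0.46 to 2.28). Against the large autosomal arms (median 12.9), and chosen after the values were seen, chromosome 4 had a higher median score of 18.4 over its 29 peaks (adjusted p = 0.00048, permutation test adjusted over 6 comparisons). The 81 peaks of the heterochromatic scaffolds had a median of 13.7, a difference of 0.79 that the permutation test did not separate from 0 (adjusted p = 0.272). The strongest peaks of chromosome 4 lay at 445271 to 445641 (60.45) and 214316 to 214983 (51.17).

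**Figure D3:**
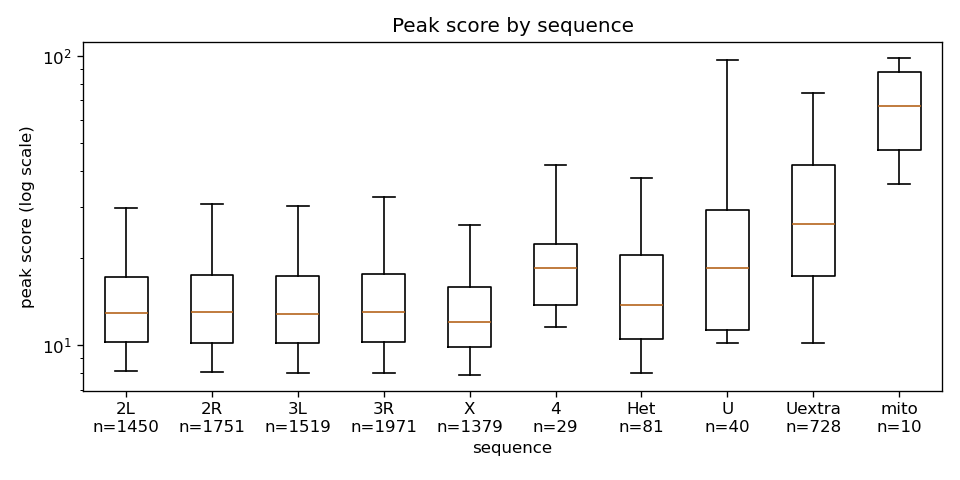
Peak score (vertical axis, log scale, the authors' unit) by sequence. Boxes give the quartiles with the median in orange, whiskers the 5th and 95th percentiles, and n the number of peaks, and mito is the mitochondrial genome. The median is 12.0 on the X, 26.1 on Uextra and 67.0 on the mitochondrial genome.

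Hairy peaks lay in clusters along the arms. Of the 8099 peaks on the arms, 86.5% had another peak within 10 kb between midpoints, against a mean of 73.6% (SD 0.51) in 1000 random placements of the same peaks on their own arms (permutation p = 0.002, two-sided, the smallest that 1000 placements can give). Within 1 kb, a distance added after the values were seen, the share was 26.5% against 7.19% on the large autosomal arms and 36.9% against 6.28% on the X. After peaks within 500 bp were joined, the mean share per 1 Mb block was 2.12% on the large autosomal arms and 1.75% on the X. Joining removes most such pairs, so the 1 kb shares cannot tell separate sites from 1 region cut into pieces. The share within 10 kb was above the highest of the 1000 placements on each of 2L, 2R, 3L, 3R and X, with an excess of 7.96 percentage points on 2R and 18.1 on the X. The random mean was 80.6% on 2R and 70.1% on the X, so an excess had less room on 2R. On chromosome 4 the share within 10 kb was 51.7% against 33.4%, within the spread of the placements (permutation p = 0.128). The densest 100 kb window, X 19500001 to 19600000, held 40 peaks, with a highest score of 26.98. It was followed by 2R 8800001 to 8900000 with 28 peaks, 2L 6900001 to 7000000 with 27, 2R 14100001 to 14200000 with 25 and 3R 17200001 to 17300000 with 25. The mean over the arms was 6.70 peaks per window. In a first set of 1000 random placements, the fullest window of a placement held a median of 17 peaks and at most 23. In the list, 11 windows held more than 23. The highest count reached in any placement of a set was between 21 and 27 over 10 further sets of 1000. Between 2 and 21 windows of the list were above it, depending on the set. The windows with 40 and 28 peaks were above the highest count of every set, and the other 3 were above that of some sets only. None of these 5 windows held a peak of the top 1% by score. Only 45 of the 8099 peaks on the arms belong to that group, so their lack in 5 windows is not unusual. The window with most peaks and the window with most strong peaks were therefore different places.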

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

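All the tests in this part were chosen after the values were seen. Peaks on sequences outside the chromosome arms were picked out because the main tests by arm left them out and their number is above 3. Passing that bound does not make their number unusual. With all nuclear sequences in the expectation, each nuclear sequence outside the arms had fewer peaks than its length predicts. Uextra had 0.47 times and U 0.07 times the expected number, with the last peak end as length. The mitochondrial genome was not in that comparison. The control libraries are not represented in the list.

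High scores were common on the mitochondrial genome, Uextra and U. The 10 mitochondrial peaks had a median score of 67.0, the 728 Uextra peaks 26.1 and the 40 U peaks 18.4, against 12.9 on the large autosomal arms (adjusted p = 0.00015 each, permutation tests that treat neighbouring peaks as independent, which those of 1 small genome or scaffold are not). Uextra held 36 of the 90 strongest peaks. Mitochondrial peaks covered 70.5% of that genome up to its last peak, and the largest gap between them was 3906 bp. On the arms, peaks covered at most 8.60% of any 1 Mb block. The mitochondrial share is below the bound of 10 times set for a multi-copy sequence that the control did not offset. This bound cannot decide, since it sets a short genome against 1 Mb blocks, and peaks covered 65.2% of a 42.0 kb stretch of 3R. That explanation stays open. At matched scores Uextra peaks were narrower than those of the large autosomal arms (mean difference of median widths -387.3 bp, permutation p = 0.0001, the smallest possible). Short scaffolds that limit the width of a peak would give this. Scores raised for any reason at unchanged widths would give it too, because score and width correlate. Without matching, the median width was 369 bp on Uextra and 380 bp on the large autosomal arms. The matched widths therefore cannot decide between these explanations. Reads from repeated sequence gathering on Uextra may raise its median by the observed 13.2, and without the sequence or the reads this cannot be told apart from binding in unplaced chromatin; no biological explanation was tested.

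The 81 peaks on the heterochromatic scaffolds had scores of 6.80 to 77.89 and a median of 13.7, which was not separated from 12.9 (adjusted p = 0.272, permutation test). The 3 strongest U peaks lay side by side between 5288464 and 5305806 and scored 145.68, 111.16 and 96.60. On Uextra 183 of the 728 peaks lay between 28 and 29 Mb, with a median score of 34.8 against 22.9 for the rest.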

How the results depend on the processing

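No paired analysis was possible because the deposited list carries no value per library, and for the same reason no replicate could be left out. The planned start site, gene feature, gene list and motif alternatives were not run, since no annotation or sequence of Release 5 was used, and no second strength measure was at hand. The 1 Mb blocks, the last peak end as length, placement within blocks, shifted windows, random placement for 50 kb blocks and removal of chromosome 4 were added after seeing the data. Clustering, the score difference between the X and the autosomes, and the score and width correlations kept their direction and their side of the threshold under every alternative run. The excess of the share with a neighbour over the random mean ran from 1.03 percentage points at 20 kb to 26.0 at 5 kb. At 20 kb the random mean was already 93.3%, so that distance had little room to show an excess. The 4479 strongest peaks had a median width of 515 bp and a median score of 18.5; merging within 500 bp gave 7515 peaks, 424 bp and 13.8. Counting 50 kb blocks ended the calls for 2R (ratio 1.10, adjusted p = 0.114) and chromosome 4 (0.72, 0.451), both by exact binomial tests, turned 2L to 1.01 and ended those of 3L and 3R. Random placement of the same peaks gave a mean of 1.02 for 2R and 0.69 for chromosome 4 (range 0.50 to 0.88). It put a peak in 98.7% of the 2R blocks on average, so this measure had little room to show an excess. The lost calls therefore do not show smaller departures in peak number. Under the other alternatives p was at most 0.00556 for 2R (permutation, unadjusted) and 0.0017 for chromosome 4 (exact, adjusted). The X kept its call with the last peak end as length and with 50 kb blocks (0.87, adjusted p = 0.0303, exact binomial test). Random placement of the same X peaks gave a mean of 0.99 (range 0.97 to 1.01) for 50 kb blocks. The 0.87 thus reflects how X peaks are spaced and is no support for fewer of them. Over 1 Mb blocks the X lost its call (ratio 0.90, permutation p = 0.245). Including all nuclear sequences, which are poor in peaks per Mb, reversed 2L to 1.18, 3L to 1.16 and the X to 1.15 times the expected number (exact binomial tests, adjusted p = 2.37e-08 for the X), since the expectation is then set by those sequences too. Among the 4479 strongest peaks the X ratio was 0.76, that of chromosome 4 was 0.52 in place of 0.32, and 2L lost its call. With windows shifted by 50 kb the densest window held 37 peaks, and the most top-1% peaks in a window fell from 10 to 6, because the 3R group was divided between windows. The unknown read depth limits statements on regions without a peak.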

Other observations

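The tests in this part were chosen after the values were seen, except the joining of peaks within 500 bp in the clustering measure, which was planned. The placement within 1 Mb blocks was added after the data were seen, with its expectation set down before its result.

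Strong Hairy peaks gathered on 3R. With scores permuted among the peaks of each arm, no window of 1000 permutations held more than 3 of the top-1% peaks, against the 10 observed between 21800001 and 21900000 (permutation p = 0.002, the smallest possible), so a chance placement of scores is argued against for these windows. The highest count was 6 with windows shifted by 50 kb, which was not set against permutations. Over the arms neighbours were weakly alike: adjacent peaks up to 10 kb apart had a Spearman rho of 0.0704 over 5417 pairs, above the highest of 1000 permutations (0.0411, permutation p = 0.002, the smallest possible). Without the 23 peaks of that window rho was 0.0644 over 5397 pairs (highest permutation 0.0440). The densest window on the X, with 40 peaks, had a median score of 12.0, which is also the median of all X peaks. The X block from 19 to 20 Mb had the highest coverage of the 117 blocks, 8.60%.

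Peaks lay closer together than random placements gave, and 2 technical explanations were tested. The first was that the peak caller had only cut single bound regions into pieces at most 500 bp apart. Joining peaks within 500 bp would then have brought the share with a neighbour within 10 kb into the random range. It was 81.0%, above the highest placement of 68.5%. If density that differs between megabases were the cause, placements kept within each 1 Mb block would have reached the observed 86.5%; their highest was 76.8%. Both are argued against as the whole cause, the first only for pieces at most 500 bp apart. Pieces of 1 region further apart than that still count as neighbours and were not tested. Clusters of genes or of regulatory regions stay open and untested, as no gene positions were used.

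Peaks on the X were of lower score, and fewer at scores of 15 or more. A constant loss of signal, as fewer X copies in a population of both sexes may give, predicts a rate ratio of 0.77 at scores of 50 or more when its factor (0.93) is taken from the medians; the observed 0.82 has an interval of 0.45 to 1.41 that holds both this value and 1, so 16 X peaks are too few to decide, and the score may not be proportional to signal. That factor predicts 0.83, 0.81 and 0.81 at scores of 15, 20 and 30 or more, above the observed intervals of 0.62 to 0.77, 0.51 to 0.72 and 0.40 to 0.76, and 0.83 at 75 or more, where the observed ratio was 1.08 (0.46 to 2.28). The medians cover listed peaks only, and a loss that took weak X peaks below the authors' threshold would bring the factor nearer to 1. The misfit of the 0.93 factor therefore does not count against a constant loss. A factor of 0.87 taken from the rate at 15 or more predicts 0.66, 0.64 and 0.78 at 20, 30 and 75 or more, within each interval. The peaks at these scores are among those that set the factor, and the interval at 75 or more is wide. This match therefore cannot decide and is no support for a constant loss. A few low-scoring blocks are argued against for the scores. Without the 5 lowest X blocks and a like share of autosomal ones the difference was -1.11 (permutation p = 2e-05). Of 22 X blocks, 21 had a median score below the autosomal block mean, although many autosomal blocks lay below it too. For the number of peaks a few poor blocks stay undecided, since the difference per block did not pass the threshold with all blocks (-7.14, permutation p = 0.245) or without the 5 poorest X blocks and a like autosomal share (-7.53, permutation p = 0.21). A different distribution of Hairy on the X stays open, as does the copy number.

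X peaks were also more often in close pairs. Per 1 Mb block, 35.6% ± 7.9 (SD, 22 blocks) of X peaks had a neighbour within 1 kb, against 26.1% ± 7.8 over 95 autosomal blocks (permutation p = 1e-05, the smallest possible). Within 5 kb the shares were 75.9% and 70.0% (permutation p = 0.00963), and after joining peaks within 500 bp they were 62.7% and 58.3%, a difference that did not pass the threshold (permutation p = 0.0875). Joined peaks within 1 kb of another made up 1.75% and 2.12% (permutation p = 0.621), a measure that joining leaves close to 0.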
